A study of Zea mays with 4 samples.

How the data were processed

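The data were raw read counts per gene from 4 RNA sequencing libraries of whole maize kernels collected 14 days after pollination, 2 from wild type and 2 from zmknl1 plants, grouped by their titles. The labels give total RNA extracted with TRIzol and sequencing on an Illumina HiSeq instrument. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic 0.36, aligned them with HISAT2 2.0.1 to the B73 RefGen_v3 genome and counted reads per annotated gene with HTSeq, and called genes with DESeq2 at a q of 0.05 and a log2 fold change of 1.5. The deposited tables hold these counts, not normalized, for 39625 gene IDs per library. The version, mode and strand setting of the counting were not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart. Reads that aligned to several places were set aside by the counting, so members of near-identical gene families, zeins above all, carry uncertain values.

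Each table ends in 5 lines for reads assigned to no gene, which were left out of library sizes and tests. Over WT replicates 1 and 2 and zmknl1 replicates 1 and 2, they included reads in no feature (5.898, 3.167, 5.031 and 4.807% of all lines), ambiguous reads (0.876, 1.215, 0.963 and 1.051%), reads of low alignment quality (5.64, 8.106, 6.462 and 6.424%), unaligned reads (12.492, 11.377, 12.243 and 11.716%) and reads aligned to several places (10.863, 23.926, 12.239 and 13.489%). The remaining 16595289 to 22725030 counts per library set the precision. No library was a copy of another: the chi-square per degree of freedom between replicate libraries was 427 in WT and 91.0 in zmknl1, far above the value of 1 that sampling noise gives.

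Counts were analysed in R 4.3.3. Genes were kept by the filterByExpr defaults of edgeR 4.0.16, which left 19519, and scaled with TMM factors of 1.10, 0.707, 1.16 and 1.10 in the order above. The main test was the edgeR quasi-likelihood F-test of zmknl1 against WT without covariates, two-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05, alone and with a log2 fold change limit of 1.5. The common dispersion corresponded to a biological coefficient of variation of 0.536. Alternatives used DESeq2 1.42.0, which gave no adjusted p for 757 genes, limma 3.58.1 with voom, other scalings, other count filters, robust empirical Bayes, the replicate number as a block, and each library left out. CPM values were computed on TMM-scaled library sizes; SDs and SEs rest on n = 2 per genotype. Standard errors of edgeR fold changes were derived from the fold change and its F statistic. Folds against a genotype at 0 counts were taken as lower bounds against a floor of 3 counts over the group, from the counts summed over each group. Floors cover counting error only.

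Gene names came from a reference table of the assembly Zm-B73-REFERENCE-NAM-5.0. It is another assembly than the one used for counting. Its chromosomes and gene order served only to place genes near 0 in 1 genotype, by chromosome and among neighbouring genes. Of the 39625 IDs, 19060 (48.1%) were found in it and 2775 had a name. Choices fixed before the data were examined were the groups, tests, alternatives, 26 gene lists and the rule for named genes. In that rule come the genes with the largest rises and falls and the smallest p past both limits with a mean CPM of at least 5, up to 3 called members per list or else the 2 with the highest mean CPM, and the 5 genes with the highest mean CPM. The 4 edgeR calls had no name. After the data were seen, the same rule was therefore applied to the DESeq2 calls. Of the 26 lists, 21 matched at least 1 named ID and 11 had the 5 tested members the list test required. No named ID matched the lists of core and linker histones, photosynthesis, cytosolic ribosomal proteins, cytokinin and cell wall, and the lists of sugar transport and of maternal pericarp had no tested member. A further 28 lists were written from the names in the reference table after that table was seen and before expression was compared, and 16 members with synonyms of another protein were left out.

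Lists were tested with camera in limma on voom values, with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists tested. With the correlation estimated from the libraries, 0 of the 6 called lists kept an adjusted p under 0.05. In that setting camera also takes its degrees of freedom from the 4 libraries, so a lost call need not reflect correlation between genes. fry was run as another alternative; it asks whether the genes of a list move on balance in a single direction, or in its mixed form in either direction, and compares no list with other genes. The edgeR, DESeq2 and limma-voom gene tests and camera at the preset correlation were run on simulated counts of 19519 genes. The simulated spread of each gene was the one edgeR estimated from the real libraries, the same in both genotypes. The other steps, among them fry, camera with an estimated correlation, the replicate block and the left-out libraries, were not simulated. Of 67 genes changed 4-fold, edgeR recovered 16 (23.9%) and DESeq2 37 (55.2%); of 67 changed 16-fold, 59 and 63; of 66 changed 64-fold, both recovered 66. False calls numbered 11 of 153 calls in edgeR and 66 of 237 in DESeq2. A simulated list of 20 shifted genes was found by camera and an unshifted list of 20 was not. Simulated genes varied independently of each other, so this does not test camera on lists of correlated genes. Summaries and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.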

Results

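Transcripts were measured by RNA sequencing in whole maize (Zea mays) kernels collected 14 days after pollination. Kernels of wild type (WT) plants were set against kernels labelled zmknl1. That label carries the name of the maize gene for KNL1, a scaffold protein of the kinetochore, the structure that attaches chromosomes to the spindle. Each genotype had 2 libraries, described as independent biological replicates from different ears. Reads counted in genes came to 20640600 in WT replicate 1, 16595289 in WT replicate 2, 19704758 in zmknl1 replicate 1 and 22725030 in zmknl1 replicate 2. The comparison asked which transcripts of the developing kernel differed between the genotypes. The reference names paired no ID with Knl1, which was not analysed here, so the labels were not checked against the level of the targeted gene.

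Across the kernel transcriptome, genes of starch synthesis, the aleurone, the embryo with its oil bodies, zeins and heat shock proteins were lower as groups in zmknl1, and genes of the basal endosperm transfer layer were higher. These 6 calls of limma camera were made with a preset correlation of 0.01 between genes. With an estimated correlation 0 of them passed (camera adjusted p from 0.333 to 0.406). Only starch synthesis then had an unadjusted p under 0.05 (0.0330). For starch synthesis and the aleurone the estimated correlation, -0.0726 and -0.184, was below the preset one, so a larger correlation cannot account for their loss. The zein call, on 5 listed genes, was also lost without WT replicate 2. Their median log2 fold change was then -0.56, while that of a wider list of 25 zeins was 1.66, in the other direction. Leaving out zmknl1 replicate 2 lost the heat shock call. Lists of kinetochore, spindle checkpoint and cell cycle genes did not pass the test. Single genes separated the genotypes sharply: GRMZM2G132077 fell from 83.8 ± 1.92 CPM in WT to 0.937 ± 0.534 CPM in zmknl1 (SD, n = 2). GRMZM2G162359 rose from 0.302 ± 0.0548 to 45.8 ± 6.41 CPM and GRMZM2G447795 from 0.174 ± 0.126 to 45.9 ± 8.43 CPM. GRMZM2G079962, with 0 counts in both WT libraries, reached 35.0 ± 2.60 CPM in zmknl1, at least 403-fold higher against a floor of 3 counts over the WT group, or 137-fold without WT replicate 1.

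Those 4 genes were all that the edgeR quasi-likelihood test called among 19519 tested genes, 3 higher and 1 lower in zmknl1, each with an adjusted p of 0.0494 and a log2 fold change beyond 1.5 in size. They had no name in the reference, and their IDs were chosen after their values were seen. At an unadjusted p under 0.05, edgeR listed 1999 genes. DESeq2, the tool the submitters named, called 299 genes higher and 380 lower, of which 294 and 369 also passed the log2 fold change limit of 1.5, and limma-voom called 0 with 2183 genes at an unadjusted p under 0.05. With library sizes taken without the 10 most abundant genes, edgeR called 0 genes, with 1997 at an unadjusted p under 0.05, and without a low-count filter it called 303 genes higher and 412 lower among 27309. All 4 edgeR genes were among the DESeq2 calls. DESeq2 also called 139 genes, and edgeR 0 with 1255 at an unadjusted p under 0.05, when both replicates 1 were set against both replicates 2. In the remaining split into pairs DESeq2 called 3 and edgeR 0 with 80 at an unadjusted p under 0.05. In simulated counts 66 of 237 DESeq2 calls and 11 of 153 edgeR calls were false, and edgeR recovered 16 of 67 genes changed 4-fold (23.9%). The simulation gave both genotypes the same spread, and its numbers of calls differed from the real ones. These shares therefore cannot be carried over to the real calls. Left-out libraries moved the edgeR count from 4 to 166 without WT replicate 1, 805 without WT replicate 2, 19 without zmknl1 replicate 1 and 35 without zmknl1 replicate 2. All 4 genes were among the calls in each of these fits.

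**Figure D1:**
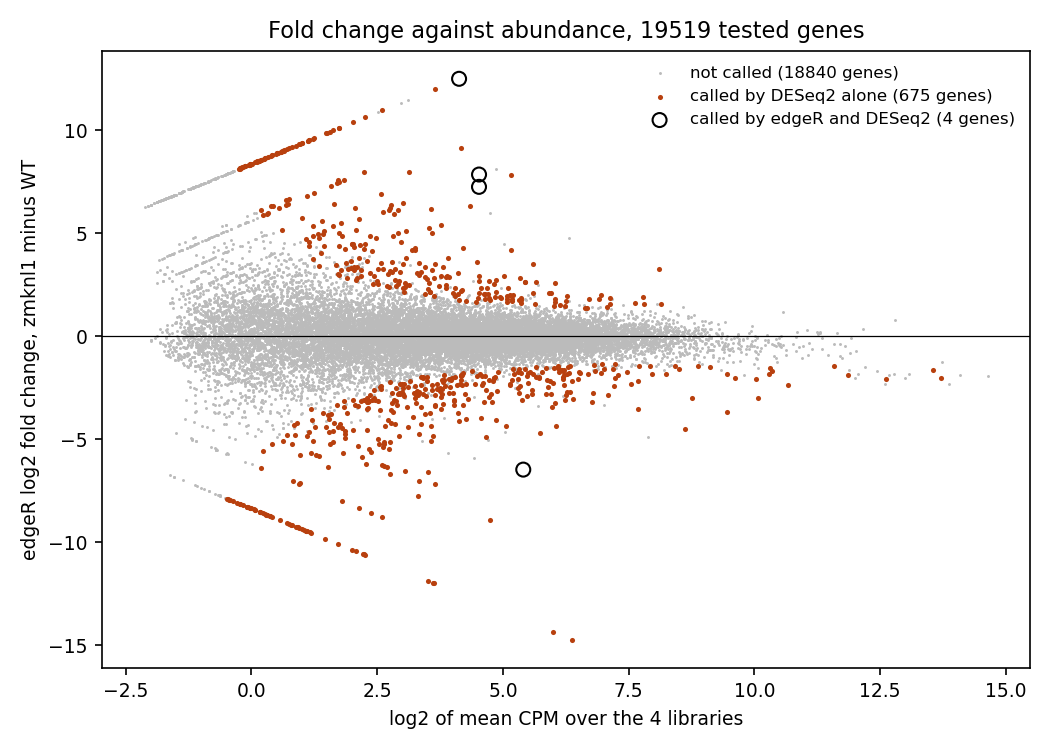
Each point is a tested gene, with the log2 of its mean CPM over the 4 libraries on the x axis and the edgeR log2 fold change of zmknl1 against WT on the y axis. Orange points are the 675 genes called by DESeq2 alone and rings the 4 called by both tools; the straight diagonals are genes at 0 counts in 1 genotype, whose fitted fold change depends on the prior count.

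The wild type libraries differed more from each other than the zmknl1 libraries did. Across genes, Pearson's r of log2 CPM was 0.866 between the WT replicates and 0.919 between the zmknl1 replicates, while WT replicate 2 and zmknl1 replicate 2 gave 0.883; genes are not independent replicates. Of 13193 genes with a mean CPM of at least 5, 875 differed by over 4-fold between the WT libraries and 216 between the zmknl1 libraries. The 10 most abundant genes took 25.251% of the counts in WT replicate 2 and 6.781% in WT replicate 1, against 6.743% and 7.77% in zmknl1. Reads aligned to several places, which were not counted in genes, made up 23.926% of WT replicate 2 and 10.863% of WT replicate 1.

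Starch genes were lower in zmknl1. The starch synthesis list, 13 genes from sucrose cleavage to glucan branching, had a median log2 fold change of -0.75, and 9 of its members lay below both WT libraries in both zmknl1 libraries (camera adjusted p = 4.4e-06). With an estimated correlation the adjusted p was 0.333. The granule-bound starch synthase gene waxy1 (GRMZM2G024993) measured 2728 ± 868 CPM in WT and 524 ± 54.5 CPM in zmknl1 (SD, n = 2), a log2 fold change of -2.38 ± 0.52 (SE), with an adjusted p of 0.251 in edgeR and 1.33e-05 in DESeq2. The sucrose synthase gene sh1 (GRMZM2G089713) measured 21383 ± 12352 CPM in WT and 5305 ± 2931 CPM in zmknl1, with a DESeq2 adjusted p of 0.0172. The ADP-glucose pyrophosphorylase subunit gene sh2 (GRMZM2G429899) had 4855 ± 1657 CPM in WT and 2751 ± 23.9 CPM in zmknl1, and agpsl1 (GRMZM2G163437) had 32.5 and 13.5 CPM in the WT libraries and 5.83 and 4.75 CPM in the zmknl1 libraries. Over all tested genes 0 members were called by edgeR, adjusted over the list alone 1 was lower, and DESeq2 called 4 lower.

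Transfer layer genes were higher in zmknl1. This layer at the base of the endosperm takes up nutrients from the maternal tissue, and its 8 listed genes had a median log2 fold change of 3.17, with 7 above both WT libraries (camera adjusted p = 2.44e-05). The estimated correlation gave an adjusted p of 0.333. Mean log2(CPM + 1) over the list was 1.34 and 2.12 in the WT libraries and 3.77 and 3.62 in the zmknl1 libraries. The marker betl4 (GRMZM2G073290) measured 1.13 ± 0.0238 CPM in WT and 15.7 ± 11.7 CPM in zmknl1 (DESeq2 adjusted p = 0.000261, edgeR 0.229), betl10 (GRMZM2G091445) 7.18 ± 8.66 and 45.6 ± 5.78 CPM, and bap2 (GRMZM2G152655) 18.6 ± 3.89 and 63.1 ± 6.53 CPM. The gene ebe2 (GRMZM2G167733) had 0 counts in WT and 4.03 ± 2.10 CPM in zmknl1. Fewer than 5 members had a mean CPM of at least 5, so the list could not be tested on those alone. Called members numbered 0 by edgeR over all tested genes, 3 higher adjusted over the list alone, and 4 higher by DESeq2. Without WT replicate 1 the median was 2.16 and without WT replicate 2 it was 7.23.

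**Figure D2:**
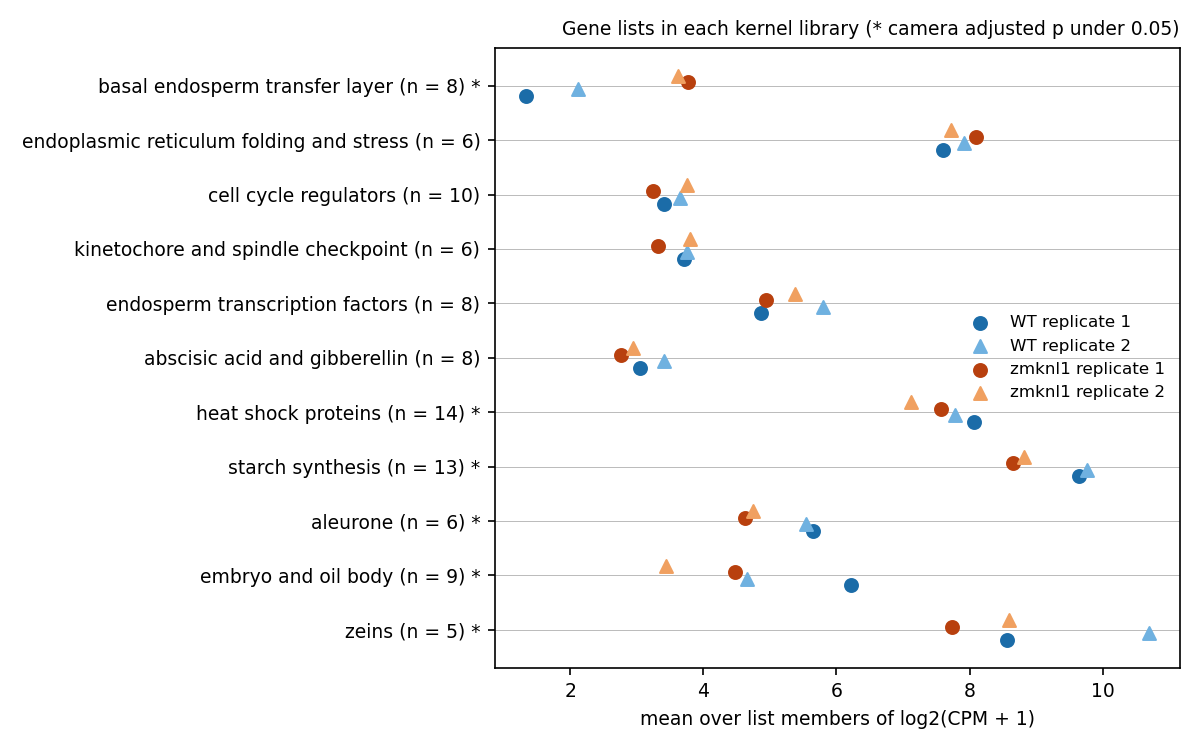
For each gene list with at least 5 tested members, points give the mean over its members of log2(CPM + 1) in each library (circles replicate 1, triangles replicate 2; blue WT, orange zmknl1), and a star marks an adjusted p under 0.05 in camera. Starch synthesis reads 9.64 and 9.76 in WT against 8.65 and 8.81 in zmknl1, and zeins 8.56 in WT replicate 1 against 10.69 in WT replicate 2.

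Zeins, the alcohol-soluble storage proteins of the endosperm, were lower in zmknl1 on the listed genes, but the difference rested on WT replicate 2. The 5 zeins had a median log2 fold change of -1.83 (camera adjusted p = 0.00157; adjusted p = 0.406 with an estimated correlation). Without WT replicate 2 the median was -0.56 and the adjusted p 0.583. A wider list of 25 zeins did not pass in camera with all libraries, no covariate and the default filter (median -1.53, adjusted p = 0.0829), though it did without a low-count filter (0.0293): 3 of its members were lower in both zmknl1 libraries, 22 overlapped, and without WT replicate 2 its median was 1.66. The 15-kDa beta-zein gene bz15 (GRMZM2G086294) measured 4011 and 7648 CPM in the WT libraries and 1083 and 2070 CPM in the zmknl1 libraries (DESeq2 adjusted p = 0.0117). The alpha-zein gene z1C2 (GRMZM2G397687, synonym floury2) had 10875 ± 14180 CPM in WT and 3063 ± 404 CPM in zmknl1 (edgeR adjusted p = 0.700). Called members numbered 0 by edgeR over all tested genes, 3 lower adjusted over the list alone, and 1 lower by DESeq2. Zein genes are near-identical copies, so values of single members are uncertain. The 5 genes with the highest mean CPM were sh1, the alpha-zein genes z1C1_4 (GRMZM2G044625), z1A2_1 (GRMZM2G008341) and z1C1_19 (GRMZM2G160739), and the unnamed GRMZM2G059620.

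Embryo and aleurone genes were lower in zmknl1 too. The embryo and oil body list, 9 genes, had a median log2 fold change of -1.02 (camera adjusted p = 0.00321; adjusted p = 0.358 with an estimated correlation). Its values also differed between the WT libraries: mean log2(CPM + 1) was 6.22 and 4.65 in WT and 4.48 and 3.44 in zmknl1. The oil body protein gene ole1 (GRMZM2G337229) measured 2156 and 449 CPM in WT and 142 and 60.1 CPM in zmknl1 (DESeq2 adjusted p = 2.06e-05), and ole17 (GRMZM2G480954) 321 and 74.9 against 30.7 and 12.1 CPM. The storage globulin gene glb2 (GRMZM2G026703) had 249 and 5.37 CPM in WT and 0 counts in zmknl1, and glb3 (GRMZM2G410134) had 143 ± 35.0 and 88.4 ± 9.93 CPM. In this list edgeR called 0 members over all tested genes, adjusted over the list alone 3 were lower, and DESeq2 called 3 lower. Medians were -0.83 without WT replicate 1, -2.25 without WT replicate 2 and -3.87 without zmknl1 replicate 1. Among the 6 aleurone genes (median -0.93; camera adjusted p = 0.00321, adjusted p = 0.333 with an estimated correlation), vp1 (GRMZM2G133398), a transcription factor of seed maturation, measured 24.6 ± 5.72 CPM in WT and 5.80 ± 2.33 CPM in zmknl1 (DESeq2 adjusted p = 0.0205). The aleurone regulators dek1 (GRMZM2G321753) and IDDveg9 (GRMZM2G129261, synonym Nkd1) had 130 ± 94.2 against 122 ± 34.3 CPM and 134 ± 9.90 against 60.3 ± 17.4 CPM. No aleurone member was called by edgeR over all tested genes, 1 was lower adjusted over the list alone and 1 by DESeq2.

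Heat shock protein genes were lower as a group in zmknl1. Their 14 members had a median log2 fold change of -0.59 and 8 lay below both WT libraries (camera adjusted p = 0.00321; adjusted p = 0.358 with an estimated correlation). The chaperone genes hsp101 (GRMZM2G360681), hsp1 (GRMZM5G802801) and hsp18a (GRMZM2G404249) measured 1961 ± 605, 475 ± 92.2 and 36.4 ± 9.92 CPM in WT and 540 ± 155, 132 ± 25.3 and 10.2 ± 3.53 CPM in zmknl1, with DESeq2 adjusted p of 0.00398, 0.00166 and 0.0296. HSP90-1 (GRMZM2G024668) and hsp70-4 (GRMZM2G340251) had 2665 ± 1313 and 4113 ± 135 CPM in WT against 2540 ± 937 and 2995 ± 87.5 CPM. Over all tested genes edgeR called 0 members, adjusted over the list alone 3 were lower, and DESeq2 called 3 lower. Without zmknl1 replicate 2 the camera adjusted p was 0.105, and the median was -0.33 without WT replicate 1 and -0.98 without WT replicate 2. In these and the preceding lists, chance alone places 33.3% of genes with both zmknl1 libraries on the same side of both WT libraries. That share counts above and below together, so it is lower for a given side. Members of a list also share the same libraries.

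The kinetochore and cell cycle lists did not pass in camera, while the listed DNA replication genes measured higher in zmknl1. The kinetochore and spindle checkpoint list (6 genes, median -0.13, camera adjusted p = 0.622) and the cell cycle list (10 genes, median -0.07, adjusted p = 0.715) had 0 members called by edgeR over all tested genes, 0 adjusted over the list alone and 0 by DESeq2. The cohesion protector gene sgo1 (GRMZM2G074082) measured 36.6 ± 6.97 CPM in WT and 36.1 ± 19.7 CPM in zmknl1, and the inner kinetochore gene CenpcA (GRMZM2G114315) 29.3 ± 6.25 and 37.6 ± 6.46 CPM. The retinoblastoma-related gene rrb1 (GRMZM2G003043) had 89.1 ± 8.40 and 68.9 ± 17.2 CPM and cyclin4 (GRMZM2G310115) 49.0 ± 10.5 and 25.5 ± 8.43 CPM. The kinesin gene krp6 (GRMZM2G114861) had 21.5 ± 9.20 and 22.9 ± 6.42 CPM. All 4 listed DNA replication genes, too few for camera, lay above both WT libraries, and MCM7 (GRMZM2G065205), a subunit of the replicative helicase, measured 10.2 ± 2.57 CPM in WT and 42.0 ± 3.41 CPM in zmknl1 (DESeq2 adjusted p = 0.00442, edgeR 0.229). Of the 4, edgeR called 0 over all tested genes and 1 adjusted over the list alone, and DESeq2 called 1. The sliding clamp gene pcna2 (GRMZM2G108712) had 40.4 ± 7.19 and 74.0 ± 31.5 CPM and MCM6 (GRMZM2G021069) 21.3 ± 8.37 and 34.3 ± 8.19 CPM. In the DNA damage list, rad51a (GRMZM2G121543), a recombinase, had 14.1 ± 1.31 and 29.1 ± 3.84 CPM and ADPRT-1 (GRMZM5G831712) 45.7 ± 30.2 and 26.0 ± 2.32 CPM.

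Other fixed lists gave no call in camera with all libraries. Without WT replicate 1 the endosperm transcription factors (median -1.06, camera adjusted p = 0.00381) and the abscisic acid and gibberellin list (median -0.57, camera adjusted p = 0.0470) passed. The endosperm transcription factors (8 genes, adjusted p = 0.596) included o2 (GRMZM2G015534), an activator of zein genes, at 846 ± 486 CPM in WT and 410 ± 87.4 CPM in zmknl1. The endoplasmic reticulum folding list (6 genes, adjusted p = 0.715) included the chaperone genes b-70 (GRMZM2G114793) at 1096 ± 2.96 and 1039 ± 437 CPM and crt2 (GRMZM2G358059) at 288 ± 0.643 and 532 ± 33.8 CPM. The abscisic acid and gibberellin list (8 genes, adjusted p = 0.177) included the receptor genes CAPIP1 (GRMZM2G165567) at 119 ± 1.11 and 62.6 ± 1.86 CPM and PYL6 (GRMZM2G141382) at 9.54 ± 4.36 and 10.6 ± 0.523 CPM. In lists under 5 tested genes, the defensin gene DEF1 (GRMZM2G153488) measured 53.1 ± 34.3 CPM in WT and 0.0999 ± 0.141 CPM in zmknl1 (DESeq2 adjusted p = 2.34e-18, edgeR 0.113), and the chitinase genes chn1 (GRMZM2G453805) and chiA (GRMZM2G051943) 0.171 ± 0.241 and 0.712 ± 0.199 against 5.26 ± 1.67 and 8.15 ± 10.3 CPM. The auxin gene GH3 (GRMZM2G378106) had 6.21 ± 1.83 and 7.50 ± 0.0138 CPM, and dad1 (GRMZM5G847530), listed under cell death, 125 ± 79.8 and 124 ± 67.3 CPM. The lipid synthesis genes DGAT1-2 (GRMZM2G169089) and FatB (GRMZM5G829544) had 38.6 ± 6.96 and 27.2 ± 0.00729 CPM in WT and 19.0 ± 2.80 and 32.9 ± 4.74 CPM in zmknl1. The embryo-surrounding region genes esr2 (GRMZM2G315601) and esr-6 (GRMZM2G048353) had 4.90 ± 6.93 and 1.15 ± 1.26 CPM in WT and 3.11 ± 2.16 and 0.908 ± 0.945 CPM in zmknl1.

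Among named genes that DESeq2 called and edgeR did not, several enzymes and regulators stood far apart between the genotypes. The myo-inositol phosphate synthase gene INO1 (GRMZM2G155242) measured 753 ± 269 CPM in WT and 32.9 ± 17.4 CPM in zmknl1 (DESeq2 adjusted p = 2.36e-14, edgeR 0.113). The reference also lists this ID as lpa1, and whether it is the lpa1 locus was not checked. The homocysteine methyltransferase gene hmt1 (GRMZM6G310687) had 51.8 ± 4.34 and 501 ± 51.7 CPM (DESeq2 adjusted p = 3.72e-12, edgeR 0.113). The alternative oxidase gene aox1 (GRMZM2G125669) had 0.344 ± 0.238 and 23.3 ± 2.46 CPM (DESeq2 adjusted p = 2.83e-12, edgeR 0.112). The potassium transporter gene kup1 (GRMZM2G084779) had 0.0439 and 0.0853 CPM in the WT libraries and 62.7 and 9.35 CPM in the zmknl1 libraries. The safener-induced gene saf1 (GRMZM2G042639) had 0 and 0.171 against 25.5 and 9.23 CPM, and the asparagine synthetase gene asn3 (GRMZM2G053669) 0.0439 and 0.171 against 20.9 and 2.68 CPM. HIT2 (GRMZM2G126765) and inra2(prp) (GRMZM2G117989) had 0.213 ± 0.301 and 0.154 ± 0.217 CPM in WT and 15.9 ± 8.27 and 13.2 ± 16.7 CPM in zmknl1. On the lower side, the transcription factor gene bHLH7 (GRMZM2G042920) had 24.8 ± 2.70 CPM in WT and 0 counts in zmknl1, at least 406-fold lower, or 194-fold without zmknl1 replicate 2 (edgeR adjusted p = 0.0535). The cytochrome P450 gene BX5 (GRMZM2G063756) and the auxin response factor gene ARF4 (GRMZM2G034840) measured 12.3 ± 13.9 and 9.90 ± 2.76 CPM in WT and 0.151 ± 0.158 and 0.219 ± 0.310 CPM in zmknl1. The receptor gene fea3 (GRMZM2G166524) had 16.7 and 9.38 CPM in the WT libraries and 0 and 0.559 CPM in the zmknl1 libraries.

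**Figure D3:**
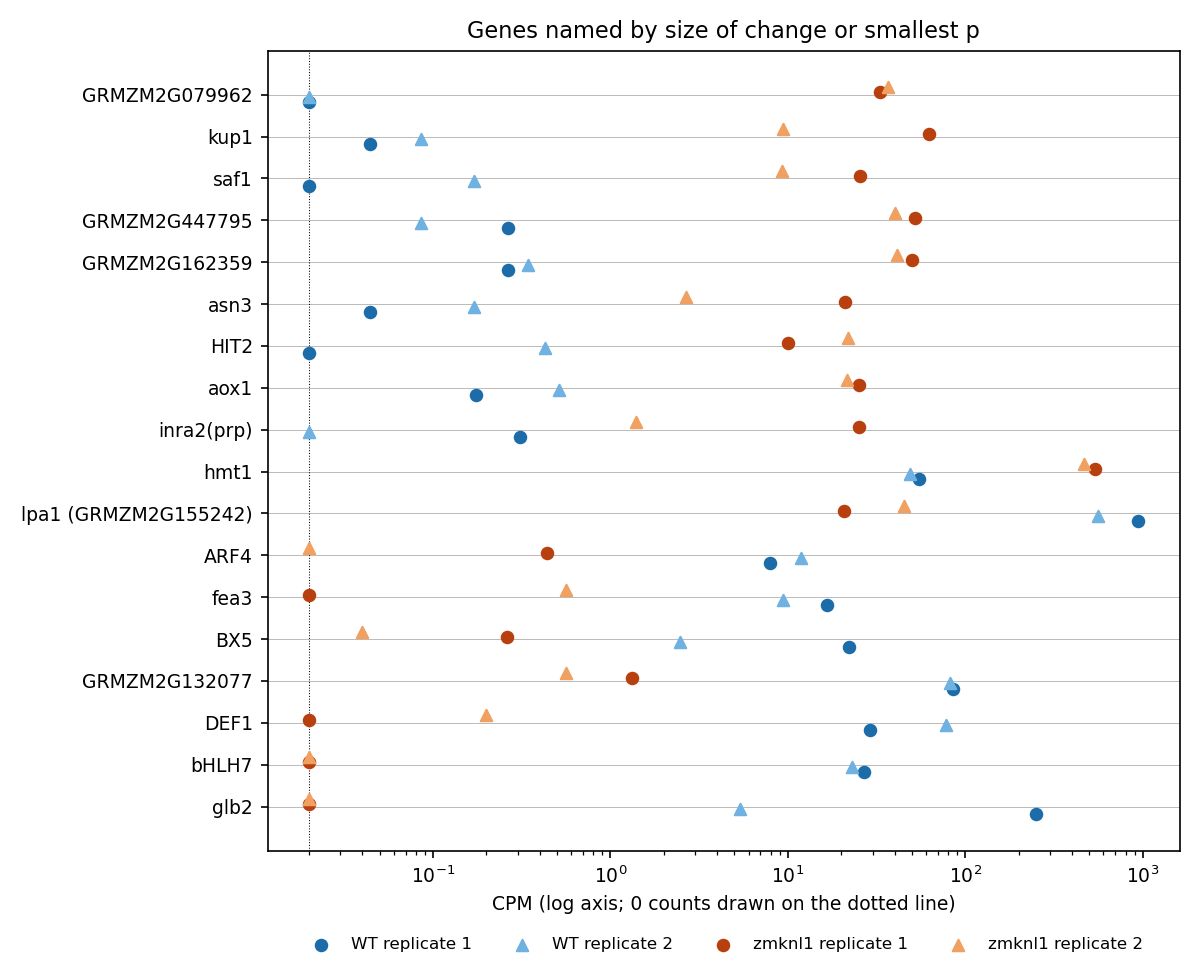
CPM on a log axis for 18 genes in each library (circles replicate 1, triangles replicate 2; blue WT, orange zmknl1), the 4 called by edgeR and those named by their size of change or p in DESeq2, with libraries at 0 counts drawn on the dotted line. The WT libraries of GRMZM2G132077 lie at 85.2 and 82.5 CPM and its zmknl1 libraries at 1.31 and 0.559 CPM.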

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

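Among the settings below, those that leave out a library, change the scaling, filter or tool were planned, and the further lists were added after the reference names were seen. The 4 counts of changed genes moved most. With the 4 edgeR calls (3 higher, 1 lower in zmknl1) as the reference, DESeq2 called 299 higher and 380 lower (294 and 369 with the fold limit), the fit without a low-count filter 303 and 412 at either limit, and limma-voom and the scaling without the 10 most abundant genes 0 and 0. Upper quartile factors, a CPM filter and robust empirical Bayes each called 4 higher and 2 lower, and DESeq2 size factors in edgeR gave 3 and 1. Counts without a library ranged from 7 to 415 higher and from 12 to 390 lower, with or without the fold limit, and the cause was not tested; with a lone library in an arm, that library is assumed to vary like the other genotype. Replicate numbers were not stated to pair libraries across genotypes, and with the replicate block edgeR called 267 higher and 375 lower (245 and 331 with the fold limit). Same-numbered deviations correlated at 0.278 across genes, but they came from 2 pairs of libraries, too few to decide a pairing. DESeq2 called 139 genes between the replicate numbers and 3 in the remaining split. The median log2 fold change of all genes moved to 0.114 without a filter, 0.10 without WT replicate 1 and 0.125 without WT replicate 2.

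The 6 called lists kept their direction in every setting that gave them a value. On members with a mean CPM of at least 5 the transfer layer list had under 5 genes and was not tested. The same held for zeins without the 10 most abundant genes. With an estimated correlation 0 lists passed the threshold at unchanged medians (aleurone -0.93, transfer layer 3.17, embryo and oil body -1.02, heat shock -0.59, starch -0.75, zeins -1.83), and fry called 2, aleurone and starch synthesis. Ranges of medians without a library were -2.45 to -0.56 for zeins, -0.98 to -0.33 for heat shock proteins and -0.60 to -0.32 for the abscisic acid and gibberellin list, which passed without WT replicate 1 (adjusted p = 0.047). DESeq2, limma-voom and robust empirical Bayes change nothing in a test on voom values and gave no list value.

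Lists without a call changed sign when a library was left out, at medians from -0.27 to 0.24 for cell cycle regulators, -0.31 to 0.48 for endoplasmic reticulum folding, -1.06 to 0.29 for endosperm transcription factors (0.12 with the replicate block) and -0.63 to 0.0540 for the kinetochore and spindle checkpoint list. Among lists added later and named in these texts the ranges were -0.11 to 0.23 for cyclins, -1.02 to 0.50 for histones, -0.0649 to 0.0508 for kinesins and tubulins, and -2.43 to 1.66 for 25 zeins, the last with an adjusted p of 3.2e-08 without WT replicate 2 (with the replicate block the zein median was -0.47, adjusted p = 4.01e-10). Further added lists without a call also changed sign: actin (-0.36 to 0.35), cytokinin (-0.48 to 0.21), the wider endoplasmic reticulum list (-0.11 to 0.21), fermentation (-0.31 to 0.37, lower with an adjusted p of 0.0107 without WT replicate 1) and jasmonate (-0.0480 to 0.61). Ribosomal proteins ranged from -0.21 to 0.84 and were higher without WT replicate 2 (adjusted p = 2.98e-05) or zmknl1 replicate 1 (0.000865) and with the replicate block (0.0206). Kernel texture and nutrient recycling genes ranged from -1.17 to 0.39 and were lower without WT replicate 1 (2.80e-08) or zmknl1 replicate 2 (0.0128), without a low-count filter (0.0466) and with the replicate block (0.000575). The cause was not tested.

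Single genes without a call changed sign over the left-out libraries: ADPRT-1 (-1.36 to 0.0870), GH3 (-0.00835 to 0.62), GRMZM2G059620 (-2.89 to 1.87), HSP90-1 (-0.50 to 0.54), PYL6 (-0.26 to 0.72), b-70 (-0.58 to 0.30), dad1 (-0.71 to 0.86), dek1 (-0.68 to 0.94), esr-6 (-2.23 to 1.77), esr2 (-1.66 to 9.20), krp6 (-0.28 to 0.60), sgo1 (-0.72 to 0.45), z1A2_1 (-3.29 to 1.15), z1C1_19 (-2.17 to 2.08), z1C1_4 (-2.83 to 1.30) and z1C2 (-2.78 to 1.86). In limma-voom esr-6 GRMZM2G048353 gave 0.0539, esr2 GRMZM2G315601 3.62, dek1 GRMZM2G321753 0.0803 and dad1 GRMZM5G847530 0.0564, with the replicate block esr2 gave 1.41, dek1 0.0995 and dad1 0.0374, and upper quartile factors gave 0.00304 for dad1. Of the other comparisons of named genes with their edgeR result, 739 stayed the same, 171 became stronger and 8 weaker. The cause of these changes was not tested.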

Other observations

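Phenylpropanoid genes and DNA replication genes were higher in zmknl1 among the lists added after the names were seen, of which 26 could be tested and 6 passed in camera. The anthocyanin and phenylpropanoid list had 8 tested genes and a median log2 fold change of 2.16 (adjusted p = 0.00266, or 0.590 with an estimated correlation), with pal3 (GRMZM2G074604), 4CL (GRMZM2G075333) and CAOMT (GRMZM5G814904) at 2.56 ± 0.238, 1.96 ± 1.57 and 0 CPM in WT and 14.3 ± 4.98, 23.1 ± 14.0 and 3.92 ± 0.277 CPM in zmknl1 (SD, n = 2). The 15 DNA replication genes had a median of 0.87 (adjusted p = 0.00857, estimated 0.590), and 13 cystatin, chitinase and inhibitor genes a median of 1.59 (adjusted p = 0.0335, estimated 0.590), among them PR10 (GRMZM2G112524) at 0.588 ± 0.349 and 26.6 ± 20.7 CPM. Wider lists of starch synthesis (23 genes, median -0.85, adjusted p = 5.0e-11, estimated 0.419), the transfer layer (15 genes, median 3.77, adjusted p = 3.13e-09, estimated 0.590) and the embryo (15 genes, median -0.69, adjusted p = 0.00857, estimated 0.740) also passed. With an estimated correlation 0 of these lists kept an adjusted p under 0.05 in camera (only the wider starch list had an unadjusted p under 0.05, 0.0161). The wider lists and the DNA replication list share members with the fixed lists, among them waxy1, ebe2, ole1 and MCM7. They therefore add no independent result.

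Several of these calls depended on a library. DNA replication did not pass without zmknl1 replicate 2 (median 0.42, camera adjusted p = 0.132). Cystatins, chitinases and inhibitors did not pass without WT replicate 2 (0.103), with a filter at a CPM of 1 (0.0798) or on members with a mean CPM of at least 5 (0.174), and their median was 0.58 without zmknl1 replicate 1 and 2.43 without zmknl1 replicate 2. The phenylpropanoid median was 3.66 without WT replicate 1, the wider transfer layer median 8.003 without WT replicate 2, and the wider embryo median -1.27 without WT replicate 2 and -2.53 without zmknl1 replicate 1. Among lists that did not pass were cyclins (14 genes, camera adjusted p = 0.793), kinesins and tubulins (24 genes, 0.732), histones (11 genes, 0.732), DNA repair (13 genes, 0.409) and zeins (25 genes, 0.0829, 22 of them overlapping between the genotypes). Without WT replicate 1, histones (0.0344), DNA repair (0.0344) and zeins (6.52e-58, lower) passed; histones also passed without zmknl1 replicate 2 (0.00390), and zeins passed without zmknl1 replicate 1 (0.0337, lower), zmknl1 replicate 2 (0.00199, lower) or WT replicate 2 (3.22e-08, higher). With all libraries and no covariate zeins also passed without a low-count filter (0.0293, lower).

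Tests on the zein gap and on the transfer layer and starch genes were chosen after those results were seen; those on genes near 0 in 1 genotype were written before, except the count by chromosome.

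All 25 tested zeins were lower in WT replicate 1 than in WT replicate 2, at a median log2 ratio of -4.22. Reads set aside because they aligned to several places were fewer in WT replicate 1, at a ratio of 0.454 to WT replicate 2, which argues against loss of such reads as the source. Dilution by embryo RNA would lower starch genes alike, but the zein median minus the starch median was -4.46 log2 units (starch interquartile range 1.22), although 12 of 15 embryo genes were higher in WT replicate 1. An unequal kernel stage or ear condition was not tested and stays open.

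In zmknl1 transfer layer genes were higher and starch genes lower. A lower share of starchy endosperm RNA, as the only change, would raise markers of all other kernel parts. Instead the embryo list changed by -1.48 against 1.97 for the transfer layer. These were 3.45 apart, beyond the larger of the ranges of these lists within a genotype, 1.57, so they did not rise alike. The embryo change by itself was smaller than that range, which lay between the WT libraries. It therefore does not show a fall of the embryo list beyond its spread. The aleurone list changed by -0.91, with mean log2(CPM + 1) of 5.65 and 5.54 in WT and 4.63 and 4.75 in zmknl1. Mean log2(CPM + 1) of the embryo list was 4.65 in WT replicate 2 and 4.48 in zmknl1 replicate 1. The values argue against a lower share alone, but not against a lower share along with lower expression of the embryo and aleurone genes themselves. Kernels at an earlier stage may have more dividing cells: DNA replication genes passed with a preset correlation (camera adjusted p = 0.0086) but not with an estimated correlation (0.590) or without zmknl1 replicate 2 (0.132), and cyclins and cell cycle genes gave 0.793, so this explanation cannot be told apart from others. That check used only lists of dividing tissue. Whether the starch, embryo and aleurone genes, lower in zmknl1 as well, followed kernel stage was not tested. A direct effect of the genotype was not tested and stays open.

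In 42 genes, 1 genotype had at most 3 counts over its libraries while the other had a mean CPM of at least 5: 25 were near 0 in WT and 17 in zmknl1. The other splits of the 4 libraries into pairs gave at most 4 such genes, and 3 splits are too few for a share under 0.05. A single linked segment would hold all of them, but the 27 that could be placed lay on 7 chromosomes, 19 of them outside the chromosome with the most, which argues against it as the whole cause wherever the others lie. For a few stretches of another strain background the test was void, since only 64.3% of the genes were placed: at most 2 lay in any 50 neighbouring genes (95th percentile of 1000 random placements, 3). Such stretches therefore cannot be told apart from an effect of the mutation.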
